A study of Mus musculus with 48 samples.

How the data were processed

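Liver RNA was measured by sequencing in mice with a floxed Bmal1 gene (symbol Arntl) and a Cre recombinase under the aP2 promoter, called KO here, and in littermate controls, called WT. Genotype, collection time and replicate number of each of the 48 libraries came from the labels. Per the labels' protocols, poly-A RNA was fragmented, primed with random hexamers, made into libraries with a TruSeq version 2 kit and 13 cycles of PCR, and sequenced on a HiSeq 2000 with 2 libraries in each lane. Each library came from a separate mouse per the labels' protocols. The labels' cell type characteristic says adipocyte while tissue and source say liver, and the samples were taken as liver. Of 23 pairs of a WT and a KO mouse with the same replicate number and time, 13 had deviations from their group means that correlated above 0.1 over 2000 genes (range −0.361 to 0.542). The numbers come from the labels, which do not say what they mark. They were taken to pair the mice at 4 h, where all 4 pairs did so (0.231 to 0.460), and at no other time. This does not show a pairing, as libraries that share a technical trend can correlate as well.

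The deposited table holds whole-number read counts per gene for 22354 genes, made by the authors. Per the submitters' processing notes CASAVA, STAR 2.4.1d and the mouse genome build mm9 were used, and gene positions are printed as the table gives them in mm9. The counting rule, the use of strand and the annotation release are not given in the sources used here, so genes that overlap or lie antisense to another, and members of near-identical families such as Mup and Cyp3a, are uncertain. The kit named in the labels does not keep strand.

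Library totals lay between 12841969 and 13009797 counts without albumin (Alb). Raw libraries usually differ by more, and whether and how they were brought to equal depth is not given in the sources used here. Alb is the only gene the table marks as high. Its values are whole multiples of 1311.61 to within 1 count and are treated as a scaled estimate, so Alb was left out of the totals and tests. Every other value is a whole number. Duplicated symbols (95) were kept apart by their gene identifiers. No column of another sample was present in the table. No pair of libraries of the same group agreed within sampling noise: the lowest chi-square per degree of freedom was 21.1.

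Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept with a minimum count of 10 and a minimum total count of 15 by the tool's own filter over the 12 groups, which left 13646 genes and removed 8707. Scaling used the TMM method. A quasi-likelihood model with 12 group means was fitted to all 48 libraries. From it came the mean KO minus WT difference over the 6 times, the difference at each time and the genotype by time interaction with 5 degrees of freedom. A second quasi-likelihood model with an intercept, a cosine and a sine term of a 24 h period for each genotype gave the rhythm tests and the test of a rhythm difference, each with 2 degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05, and all tests were two-sided or F tests. The standard error of a log2 change is its size divided by the square root of F. Amplitude and peak time came from least-squares fits of the same harmonic to log2 normalised counts (CPM, scaled with the TMM factors) with a prior count of 2, and an amplitude is the distance from mean to peak in log2 units. A peak time is given in hours after the first collection time.

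The comparisons, the rule for named genes, 25 gene lists and most alternatives were fixed before the data were examined. The rule takes Arntl, all tested members of the core clock and clock output lists, the 10 largest changes in each direction across times among genes with a mean of at least 1 CPM and no predicted-gene name, the 3 lowest p-values past the threshold at each time, the 10 lowest for the interaction and for the rhythm difference, and the 10 largest WT amplitudes. The values of 1 named clock gene are not reported here. The rule also takes up to 4 members of each list by lowest p, and 5 genes described as not past the test where none passed. The lists were core clock, clock output, fatty acid synthesis, cholesterol synthesis, PPARalpha targets and fatty acid oxidation, glucose metabolism, bile acid metabolism and transport, xenobiotic metabolism, acute phase and inflammation, male-biased and female-biased liver genes, heat shock, ER stress and amino acid response, interferon response, proliferation, growth hormone and glucocorticoid response, and mitochondrial genome transcripts. Further lists held markers of adipocytes, macrophages and Kupffer cells, endothelium, stellate cells and fibroblasts, bile duct, lymphocytes, red blood cells and pancreas. No mitochondrial genome transcript was among the genes of the table, so 24 lists were tested. The list test was camera in limma 3.58.1 with a correlation estimated per list, on the difference across times. Lists of immediate early genes, matrix and portal stroma genes, Mup genes and adrenal cortex markers were added after the results were seen.

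Alternatives were other scaling (RLE size factors, totals only), no low-count filter or a mean of at least 10 CPM, DESeq2 1.42.0, a robust edgeR fit, the library number as covariate, libraries of a single time alone, no 16 h groups, replicate blocks, a 5 degrees of freedom rhythm test, camera with a preset correlation of 0.01, fry, and each library left out in turn. Added after seeing the data were a fit with Alb, removal of each library's trend with transcript GC content (lowess span 0.3, GENCODE vM21 matched by gene identifier for 97.6% of the tested genes), and a fit without 3 libraries with unusual gene content. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

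The differences across times and at 0 h, the interaction, the rhythm fits and the list test were tried on simulated counts. These had the real means and depths, with 200 changed genes or 1 changed list. Genes were drawn independently and without a GC trend. The false calls and the list result therefore do not carry over to real libraries that share such a trend. The alternatives, splits and shuffles were not simulated. For the difference across times, 60.0% of genes changed by 0.5 and 91.0% of those changed by 1 on the log2 scale were found among 13466 genes, with 5 false calls of 156. For the difference at 0 h the shares were 2% and 30.0%. For the interaction, 11.0% of changes of size 1 and 53.0% of size 2 were found among 13475 genes. WT rhythms of amplitude 0.5 and 1 were found in 50.0% and 91.0% of cases and rhythm differences of those sizes in 25.0% and 63.0%, among 13468 genes. The list test found the 1 changed list of 24.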

Results

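The liver transcriptome was measured at 6 times over 20 h in mice carrying a floxed Bmal1 gene and an aP2-driven Cre, a driver used for adipocytes, and in littermate controls (WT). Bmal1, listed under its gene symbol Arntl, encodes the activating partner of CLOCK and NPAS2 in the circadian clock. The mice had spent 36 h in darkness and were killed in darkness at 0, 4, 8, 12, 16 and 20 h. The comparisons ask how loss of the clock gene under this driver relates to gene expression and its rhythm in liver. There were 25 WT and 23 KO libraries, 4 in each group except at 16 h, where the labels give 5 WT and 3 KO, while the design text gives 4 mice for every group. Total counts without albumin lay between 12841969 and 13009797 (median 12929297), so these totals were nearly equal, which does not show an equal sequencing depth. P-values called adjusted are Benjamini-Hochberg values of edgeR's quasi-likelihood test unless another test is named, log2 changes are KO minus WT with their standard errors (SE), and CPM values are counts scaled to a common library size with TMM factors.

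The sex of the mice was read from sex-linked genes. Xist, which is expressed from the inactive X chromosome of females, had 3029 to 13969 counts in every library. The Y-linked genes Kdm5d, Uty and Eif2s3y had a total of 1 count each, and no library had more than 1 count over all 3 genes. These counts argue for female mice in every library, while the design text describes the mice as male. Some libraries stood apart. WT_0h replicate 3 held genes of adrenal steroid synthesis (Star 336 counts against a median of 25 over all libraries, Cyp11a1 127, Cyp21a1 439) and 111674 counts of the acute phase gene Saa1, against a median of 593. KO_0h replicate 2 held the pancreatic enzyme genes Cela2a (907 counts) and Prss2 (524 counts). KO_16h replicate 2 had 5936 counts of the leptin receptor gene Lepr, and Saa1 was also high in KO_4h replicate 2 (54369 counts) and KO_20h replicate 1 (29715 counts).

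Arntl (ENSMUSG00000055116, mm9 chromosome 7, 120350979 to 120457636) was expressed in every group of both genotypes and cycled in both. In WT it averaged 37 ± 5.9 CPM (SD, n = 4) at 0 h, 21.1 ± 9.3 (n = 4) at 4 h, 2.14 ± 0.71 (n = 4) at 8 h, 2.01 ± 1.12 (n = 4) at 12 h, 16.2 ± 2.9 (n = 5) at 16 h and 32.3 ± 3.7 (n = 4) at 20 h. In KO it averaged 32.4 ± 4.0 CPM (n = 4) at 0 h, 9.53 ± 2.75 (n = 4) at 4 h, 3.67 ± 2.14 (n = 4) at 8 h, 6.34 ± 5.15 (n = 4) at 12 h, 26.3 ± 8.7 (n = 3) at 16 h and 32.1 ± 3.5 (n = 4) at 20 h. Its mean difference over the 6 times was 0.30 ± 0.16 on the log2 scale and did not pass the test (edgeR adjusted p = 0.347). The counts are per gene, so the floxed part was not measured separately, and liver levels do not check a deletion aimed at fat.

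**Figure D1:**
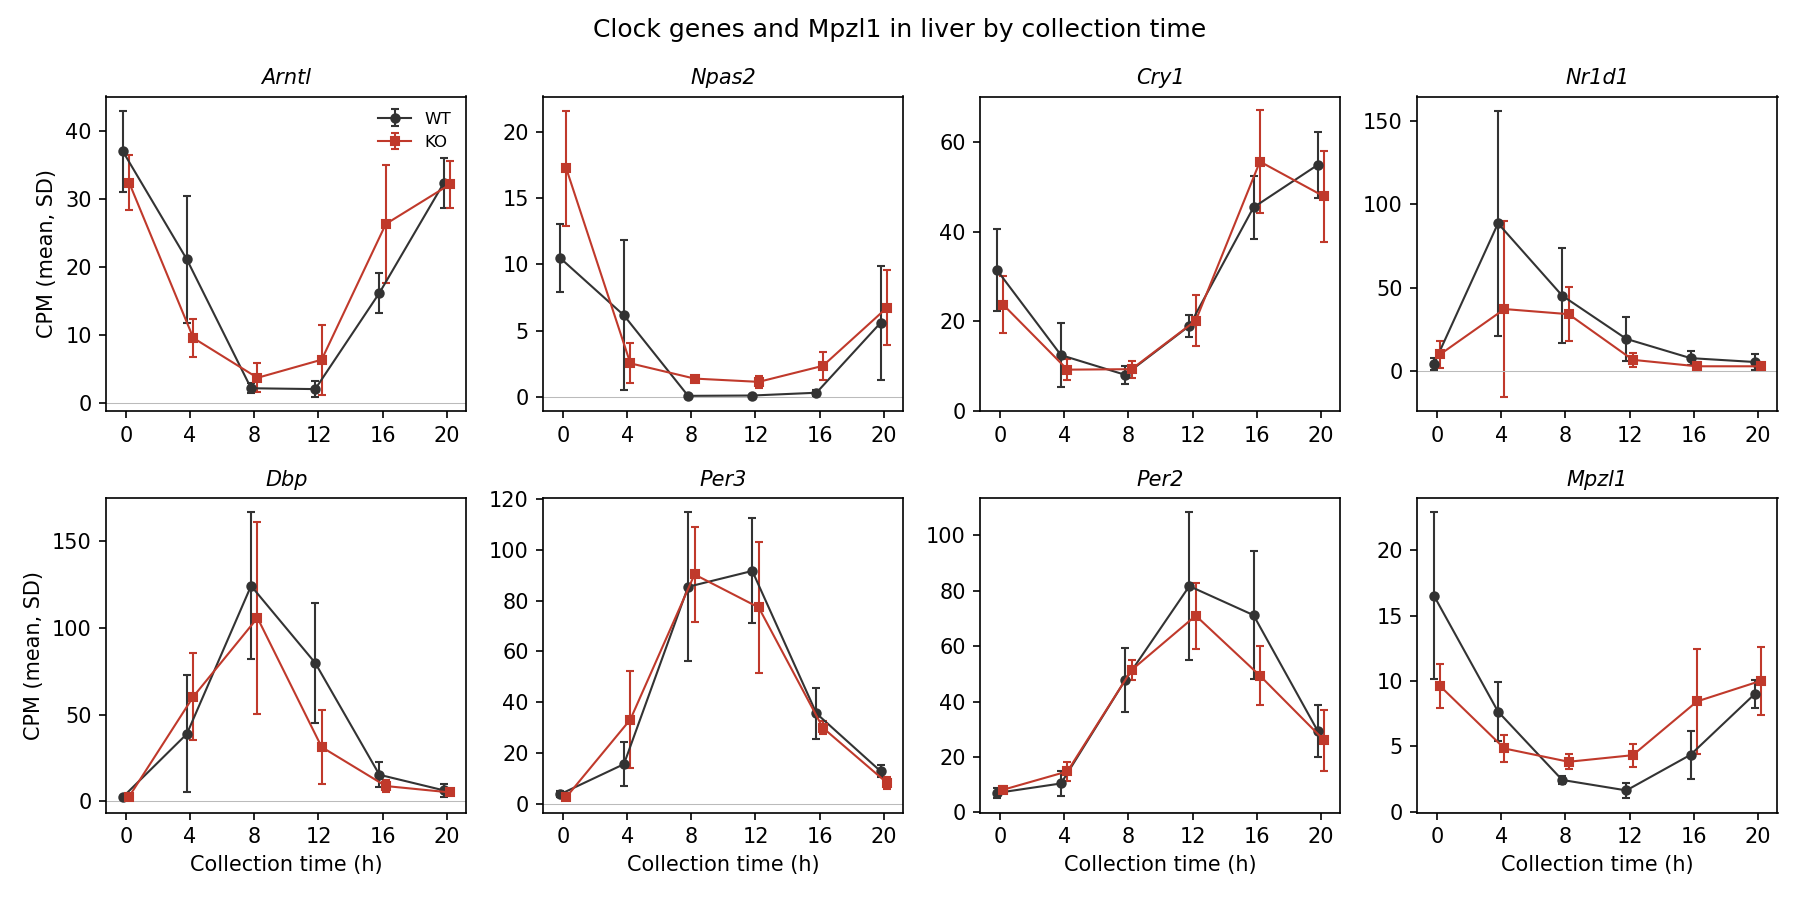
Expression of 8 clock and clock-related genes over the 6 collection times in WT and KO liver, as mean CPM on a linear axis with SD error bars (n = 4 per group, 5 WT and 3 KO at 16 h) against hours after the first collection. Arntl reached 37 CPM in WT and 32.4 CPM in KO at 0 h, and Npas2 stayed above 1 CPM in KO at 8 and 12 h, where WT means were 0.0742 and 0.0994 CPM.

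Across the 6 times, the most clearly lower genes of KO liver included signalling genes that respond within minutes to stress. Dusp1, which encodes a phosphatase of MAP kinases (mm9 chromosome 17, 26642535 to 26645464), fell from 77.8 to 26.7 CPM on average (log2 change −1.64 ± 0.18, adjusted p = 1.7e-07). Fos and Jun, the partners of the AP-1 transcription factor, fell by 1.98 ± 0.26 and 1.19 ± 0.23 on the log2 scale (adjusted p = 4.8e-06 and 0.00290), and Gadd45g, a growth arrest and DNA damage gene, fell by 1.34 ± 0.34. Serpine2, a serine protease inhibitor, fell by 1.27 ± 0.22, Podn, a matrix proteoglycan, by 1.25 ± 0.22, and Cpxm1, a carboxypeptidase family member, by 2.45 ± 0.40. The other genes of the 10 largest decreases were Aim1l (−2.10 ± 0.26), the meiotic cohesin gene Rec8 (−1.82 ± 0.22) and the immunoglobulin heavy chain gene Ighm (−1.63 ± 0.44), which was lower at only 4 of the 6 times. The other 9 were lower at all 6 times, except Gadd45g at 5.

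Genes that rose in KO liver included members of multigene families and the clock gene Npas2. Serpinb1a, an inhibitor of neutrophil proteases (chromosome 13, 32933961 to 32943054), rose from 34.7 to 118 CPM (log2 change 1.73 ± 0.29, adjusted p = 6.6e-04). Npas2 (chromosome 1, 39250576 to 39420079) rose by 1.67 ± 0.27 and was higher at 5 of the 6 times (adjusted p = 3.7e-04). This mean log2 change came largely from 8, 12 and 16 h, where WT averaged only 0.0742, 0.0994 and 0.310 CPM. KO averaged 1.38, 1.13 and 2.34 CPM at these times. The WT and KO means were 10.5 and 17.3 CPM at 0 h, 5.59 and 6.74 CPM at 20 h, and 6.15 and 2.53 CPM at 4 h. Of the genes given here, the largest rises were in Cyp3a16 (2.52 ± 0.59) and Cyp3a41b (2.49 ± 0.58), female-enriched cytochrome P450 genes. The major urinary protein genes Mup17 (1.89 ± 0.44), Mup15 (1.78 ± 0.45), Mup12 (1.59 ± 0.39) and Mup16 (1.22 ± 0.32) also rose. The interferon-inducible GTPase gene Gbp10 rose by 1.16 ± 0.25 and the glucuronosyltransferase gene Ugt2b37 by 1.15 ± 0.26, which was lost with both 16 h groups left out (edgeR adjusted p = 0.0791). The Cyp3a and Mup values are uncertain because near-identical copies may share reads, and they varied widely between mice. Cyp3a16 ran from 1.04 to 546 CPM in KO_16h and from 0.170 to 281 CPM in WT_16h.

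**Figure D2:**
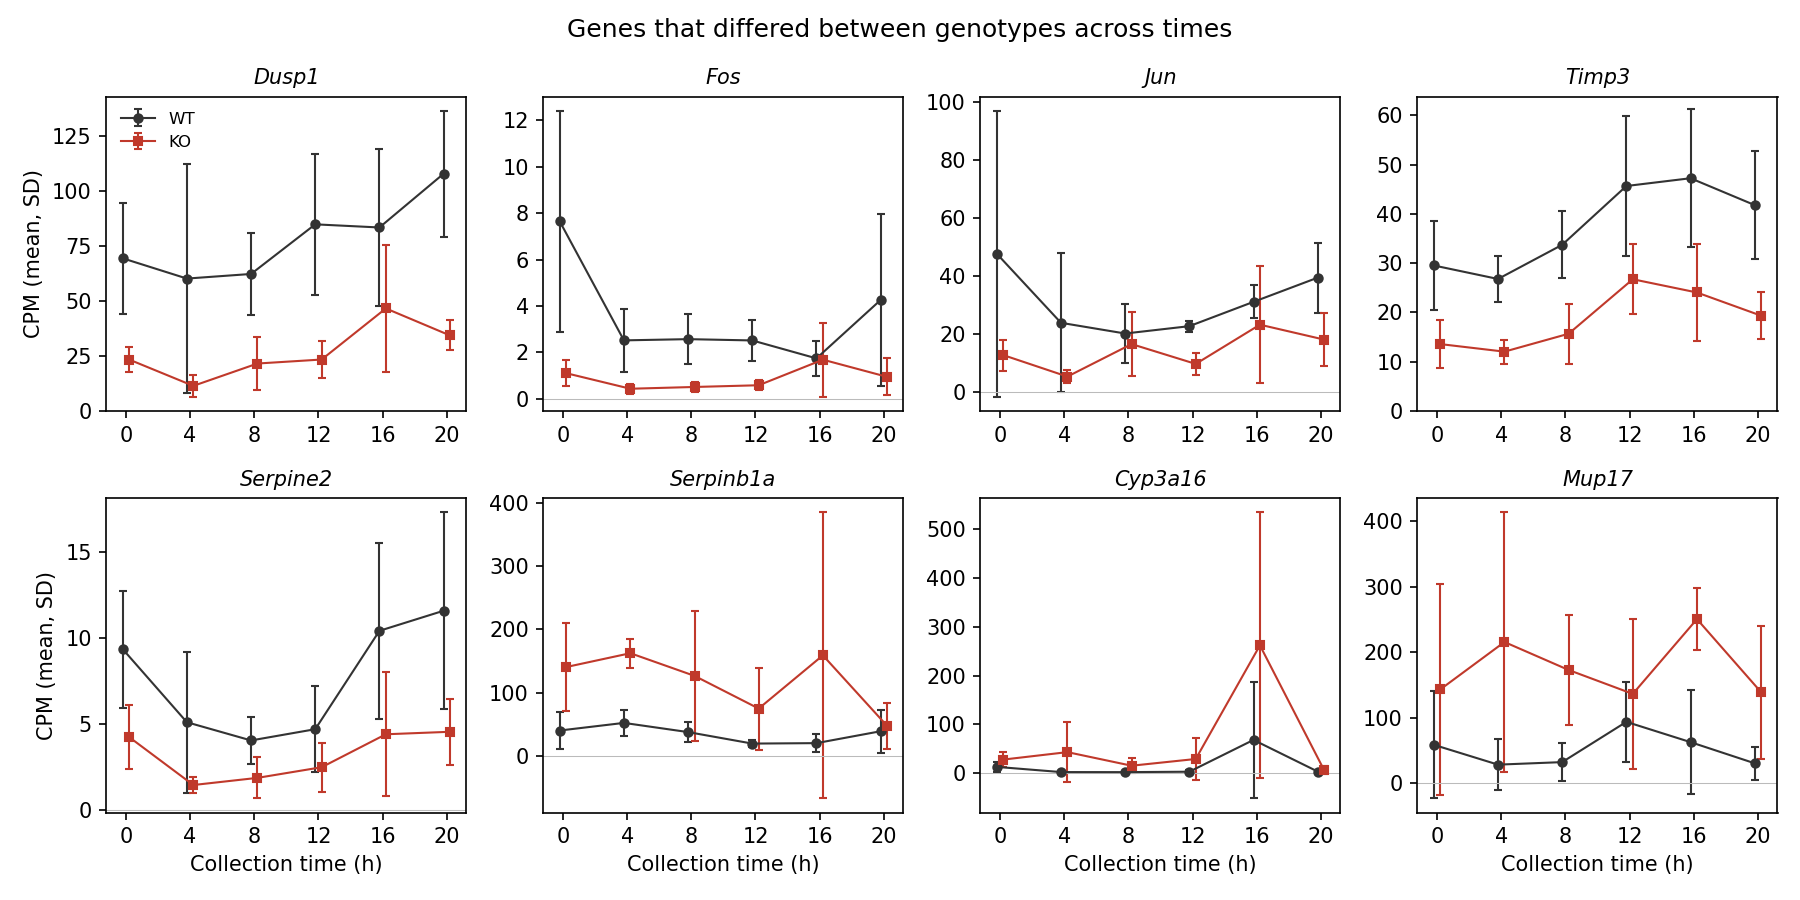
Expression of 8 genes that differed between genotypes across times, as mean CPM with SD error bars (n = 4 per group, 5 WT and 3 KO at 16 h) against hours after the first collection. Dusp1 averaged 77.8 CPM in WT and 26.7 CPM in KO, and Serpinb1a 34.7 and 118 CPM.

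In all, 191 of 13646 genes differed between the genotypes across times, 85 higher and 106 lower in KO, and 145 of them had the same direction at all 6 times. The change exceeded 1 on the log2 scale for 42 of them, 28 had a mean under 1 CPM and 7 were Mup genes, with the pseudogene Mup-ps14 counted, which was chosen for naming after its values were seen. DESeq2 called 356 genes. The edgeR count was 484 without KO_4h replicate 1, 125 without KO_4h replicate 3, 381 without WT_16h replicate 2, 328, 363 and 99 without KO_16h replicates 1, 2 and 3, and 303 without the 3 libraries with unusual gene content.

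Several of these calls lay close to the threshold. Without KO_20h replicate 2, Cyp3a16, Cyp3a41b and Mup12 no longer passed the edgeR test (highest adjusted p over their alternatives 0.0641, 0.0966 and 0.103), and Mup12 was also lost without KO_12h replicate 3 or KO_16h replicate 3. Their log2 changes stayed at 2.20, 2.27 and 1.35 or above in the alternatives run. Mup15 was lost without KO_0h replicate 1, KO_4h replicate 3 or 4, or KO_12h replicate 1 (up to 0.0639), with a change of at least 1.58 in the alternatives run. Gadd45g was lost without WT_4h replicate 2, KO_4h replicate 3, WT_8h replicate 4, WT_12h replicate 4 or KO_16h replicate 3 (up to 0.0746), with changes between −1.84 and −1.09 over the alternatives run. Ighm was lost in 45 of 60 alternatives, with an adjusted p of up to 0.333, its change was −0.98 without WT_16h replicate 5 and −1.04 without WT_12h replicate 3, and its WT_16h mean of 251 ± 525 CPM (SD, n = 5) came from libraries between 5.09 and 1189 CPM. Mup16 was lost in 33 alternatives (up to 0.0862), with a change of at least 1.08 in those run.

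**Figure D3:**
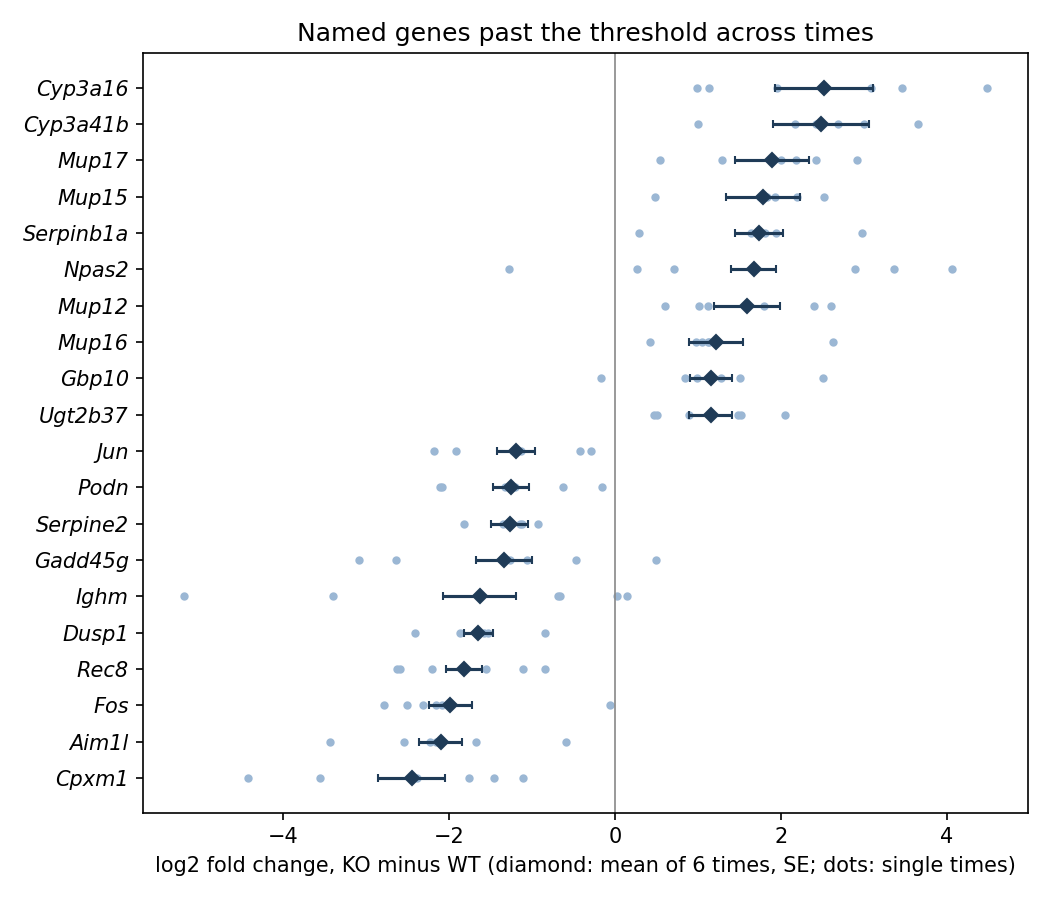
Log2 change KO minus WT of the 20 named genes of the comparison across times. Diamonds are the mean of the 6 times with its SE and dots are the changes at single times, from −2.45 for Cpxm1 to 2.52 for Cyp3a16.

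Of 20 interferon-response genes tested, 19 had a positive change in KO. Ifit1 (0.79 ± 0.17, adjusted p = 0.00804), Usp18 (0.50 ± 0.11, 0.0133), Isg15 (0.52 ± 0.14, 0.0379) and Gbp3 (0.65 ± 0.18, 0.0488), all induced by interferon, rose, and 16 did not pass by edgeR. Adjusted over the list alone, 11 rose. Isg15 was lost in 22 alternatives, Gbp3 in 44 and Usp18 with both 16 h groups left out (edgeR adjusted p = 0.0821). Camera with a preset correlation called the list (adjusted p = 4.5e-09) and fry did so as well (adjusted p = 0.0444), but with an estimated correlation the p was 0.0241 and the adjusted p = 0.434.

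Lipid and energy genes showed few calls. Among 25 PPARalpha targets and fatty acid oxidation genes, the fatty acid transporter gene Cd36 (0.74 ± 0.14, adjusted p = 0.00326) and the pantetheinase gene Vnn1 (0.68 ± 0.16, 0.0219) rose and 23 did not pass, with 2 adjusted over the list alone. Vnn1 was lost without KO_16h replicate 3 (up to 0.0590). Fabp1 had a change of 0.50 ± 0.18 that did not pass, but did without KO_16h replicate 2 (0.58 ± 0.15, edgeR adjusted p = 0.0226), and was at 0.28 ± 0.16 without KO_16h replicate 3. Of 16 glucose metabolism genes, the serine dehydratase gene Sds fell (−0.80 ± 0.19, adjusted p = 0.0238), 15 did not pass, and 1 fell adjusted over the list alone. Pck1 (−0.43 ± 0.17) and Tat (−0.45 ± 0.19), which serve gluconeogenesis and tyrosine breakdown, were among those that did not pass. Without KO_16h replicate 2 both passed by edgeR, Pck1 at −0.57 ± 0.16 (adjusted p = 0.0486) and Tat at −0.75 ± 0.16 (0.00652). None of 19 fatty acid synthesis genes passed by edgeR, with 1 higher adjusted over the list alone. Elovl5 was at 0.47 ± 0.14 and Srebf1 at −0.54 ± 0.24, and the list's median of −0.01 differed in sign from the upward direction of its test. None of 23 cholesterol synthesis genes passed, also adjusted over the list alone, with Sc4mol at 0.59 ± 0.24 and Cyp51 at 0.44 ± 0.22. With an estimated correlation the adjusted p of camera was 0.512 for the PPARalpha list and 0.632 for cholesterol synthesis, against 0.00341 and 0.0483 with the preset correlation.

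Among the genes of the fixed male-biased and female-biased liver lists, 1 passed over all genes. Cyp3a41b, given above as female-enriched, also passed but is on neither list. Of 15 female-biased genes, Cyp3a16 rose, 14 did not pass, and 4 rose adjusted over the list alone, with Cyp2b9 at 0.25 ± 0.07, Cyp2b13 at 0.49 ± 0.16 and Prom1 at 0.61 ± 0.21. None of 14 male-biased genes passed. Adjusted over the list alone, 4 were higher and 2 lower, among them the oxysterol hydroxylase gene Cyp7b1 (0.31 ± 0.10), Nudt7 (0.35 ± 0.12) and Gstp1 (−0.66 ± 0.24). The male-biased median was −0.10 while its camera direction was up. With an estimated correlation the female-biased list had a p of 0.0441 (adjusted p = 0.434), against an adjusted p = 0.00341 with the preset correlation.

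Among stress and growth genes, Rrm2, a subunit of ribonucleotide reductase, was lower (−0.91 ± 0.16, adjusted p = 0.00146). It was the only 1 of 15 proliferation genes past the threshold, also adjusted over the list alone. Of the 15, 13 had a negative change, with a list median of −0.37, and Birc5 was at −0.37 ± 0.15. Of 16 growth hormone and glucocorticoid response genes, the glucocorticoid-induced Fkbp5 fell (−0.65 ± 0.18, adjusted p = 0.0488) and 15 did not pass. With Sgk1 (−0.44 ± 0.12), 2 fell adjusted over the list alone, and Fkbp5 was lost in 37 alternatives. None of 16 heat shock genes passed by edgeR. Adjusted over the list alone, 5 chaperone genes were higher and 1 gene lower, led by Hspd1 (0.22 ± 0.06), Hspe1 (0.32 ± 0.10) and the cold-inducible Cirbp (−0.39 ± 0.13). With an estimated correlation camera gave an adjusted p = 0.434 for proliferation and for heat shock, against 0.00362 and 0.0150 with the preset correlation. None of 20 ER stress and amino acid response genes and none of 19 acute phase genes passed, with 0 adjusted over the list alone. Pdia6 was at 0.20 ± 0.09, Herpud1 at −0.27 ± 0.12, Socs3 at −0.51 ± 0.17 and Hp at −0.27 ± 0.11.

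Of 22 xenobiotic metabolism genes, Cyp2c37 rose (0.50 ± 0.12, adjusted p = 0.0228), also adjusted over the list alone, and 21 did not pass. It was lost without KO_16h replicate 3 (up to 0.109) and with both 16 h groups left out. The constitutive androstane receptor target Cyp2b10 was at −0.70 ± 0.28 and did not pass, but did without KO_16h replicate 2 (−0.97 ± 0.27, edgeR adjusted p = 0.0375). None of 16 bile acid genes passed, also adjusted over the list alone, with Slco1b2 at 0.38 ± 0.14 and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 0.56 ± 0.28.

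Markers of other cell types gave a single call. Of 13 lymphocyte markers Ighm fell, 12 did not pass, and 1 fell adjusted over the list alone, with Cd3e at −0.75 ± 0.32. None of 12 stellate cell and fibroblast markers passed over all genes, and adjusted over the list alone 2 were lower, Des (−0.34 ± 0.10) and Hand2 (−0.52 ± 0.15). Likewise 2 of 7 bile duct markers were lower adjusted over the list alone, with Krt7 at −0.49 ± 0.15 and Sox9 at −0.37 ± 0.14. Of 6 adipocyte markers, 2 were higher and 1 lower adjusted over the list alone, from Plin4 (−0.63 ± 0.21) to Lpl (0.49 ± 0.18) and Car3 (0.74 ± 0.29). The 2 tested pancreas markers, Cela1 (0.52 ± 0.18) and Cela2a (1.23 ± 0.53), were higher adjusted over the list alone, but at 0.25 ± 0.12 and 0.47 ± 0.33 without KO_0h replicate 2, the library with pancreatic transcripts. None of 15 macrophage and Kupffer cell markers (Lyz2 0.25 ± 0.19, Timd4 0.21 ± 0.20), 12 endothelial markers (Clec4g 0.31 ± 0.14, or 0.20 ± 0.13 without KO_16h replicate 3, Eng −0.20 ± 0.12) and 5 red blood cell markers (Hbb-b2 0.45 ± 0.32, Alas2 0.20 ± 0.17) passed, also adjusted over the list alone. Over the 24 lists, camera with an estimated correlation called 0, with 2 at an unadjusted p under 0.05, while 6 were called with the preset correlation and 1 by fry.

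Some list genes given above as not past the edgeR test over all genes passed with a library left out. Besides those already stated, Elovl5, Socs3, Cyp2b9, Cyp2b13, Sgk1, Des and Hand2 did so without KO_16h replicate 2, and Hspd1, Hspe1, Cirbp, Sgk1, Plin4, Des, Hand2 and Cd3e without KO_4h replicate 1. Without WT_16h replicate 2 these were Elovl5, Cyp2b9, Hspd1, Hspe1, Sgk1, Des, Hand2 and Krt7, and without KO_16h replicate 1 Hspd1, Hspe1, Plin4 and Krt7. Other single libraries did so for Elovl5, Cyp2b9, Hspd1, Sgk1, Des, Hand2 and Krt7.

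At 0 h the genes that differed were Cela2a, a pancreatic elastase gene higher in KO (log2 change 6.09 ± 1.08, adjusted p = 0.0203), and Star, which carries cholesterol into mitochondria for steroid synthesis and was lower in KO (−2.59 ± 0.49, adjusted p = 0.0332). Cela2a was at 69.0 CPM in KO_0h replicate 2 and at 0.524 to 0.936 CPM in the other KO_0h libraries, and Star at 26.5 CPM in WT_0h replicate 3 and at 2.52 to 3.18 CPM in the other WT_0h libraries. These are the libraries with pancreatic and adrenal transcripts. The change of Cela2a was 1.52 ± 0.76 without KO_0h replicate 2 and that of Star −0.97 ± 0.35 without WT_0h replicate 3, and without the 3 unusual libraries neither gene remained among 8 called. Both genes missed the threshold without KO_0h replicate 2 or WT_0h replicate 3, and Star also when any other single KO_0h library was left out (edgeR adjusted p up to 1). DESeq2 called 11 genes. The edgeR count was 0 without WT_0h replicate 3, 7, 7 and 9 without WT_0h replicates 1, 2 and 4, and 1 without KO_0h replicate 1, 3 or 4, and libraries of other times moved it to at most 6.

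At 4 h, 5 genes fell in KO and none rose. Dusp1 was at 60.1 ± 52.1 CPM in WT and 11.3 ± 4.9 CPM in KO (SD, n = 4 each, log2 change −2.40 ± 0.44, edgeR adjusted p = 0.0361), a change of −1.59 without WT_4h replicate 2. Rec8 fell by 2.59 ± 0.51 and the kinase gene Map4k4 by 1.09 ± 0.22 (adjusted p = 0.0439 each). The remaining genes, Tmem171 (−5.85 ± 1.18) and Wfikkn1 (−2.74 ± 0.56), lay under 1 CPM on average and were chosen for naming after their values were seen. Mice of this time with the same replicate number were also fitted as pairs, as all 4 pairs had correlated deviations. The labels do not say what these numbers mark. With the pairs as blocks 2 genes passed, Rec8 (−2.64 ± 0.44) and Gbp10, which rose (2.74 ± 0.47, edgeR adjusted p = 0.0490 each), while Dusp1 was at −2.13 ± 0.40 (0.0786), Wfikkn1 at −2.66 ± 0.52 (0.0796), Map4k4 at −1.10 ± 0.24 (0.0986) and Tmem171 at −5.85 ± 1.32 (0.106). The libraries of this time differed in their trend with transcript GC content, given as a slope in log2 units per 10 percentage points of GC. The slope was 0.48 in KO_4h replicate 1 and −0.35, −0.80 and −0.68 in KO_4h replicates 2, 3 and 4. In WT_4h replicates 1, 2, 3 and 4 it was 0.52, 0.33, 0.02 and −0.02. Replicate 1 had the highest slope in both genotypes, so this trend could also give the correlated deviations, and a pairing is not shown. The count was 3354 without KO_4h replicate 1, 0 without WT_4h replicate 2, KO_4h replicate 2, 3 or 4, or WT_20h replicate 4, 1 without WT_4h replicate 1, 322, 31 and 12 without KO_16h replicates 3, 2 and 1, and 192 by DESeq2. Of the 48 libraries, 35 moved it by over 1.5 times when left out.

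At 8 h edgeR called 0 genes, with 248 of 13646 at an unadjusted p under 0.05 and 2 by DESeq2. Chance alone gives a share of 0.05 on average, and the shares at 8, 12 and 20 h all lay below it. At 0, 4 and 16 h the counts at an unadjusted p under 0.05 were 754, 3175 and 907. The lowest p-values belonged to Npas2 (4.07 ± 0.83, adjusted p = 0.236) and Endod1 (1.02 ± 0.25), both higher in KO, and to Timp3 (−1.10 ± 0.30), Dusp1 (−1.53 ± 0.43) and Fos (−2.31 ± 0.65), which were lower. The count was 1 without WT_4h replicate 2 or WT_20h replicate 2. At 12 h edgeR also called 0 genes, with 600 at an unadjusted p under 0.05 and 3 by DESeq2. The lowest p-values were those of Aim1l (−3.43 ± 0.65, adjusted p = 0.0681), the peroxidasin gene Pxdn (0.88 ± 0.19, 0.186), Dusp1 (−1.86 ± 0.43, 0.322), Mpzl1 (1.39 ± 0.32, 0.322) and Npas2 (3.36 ± 0.83, 0.469). The count was 2 without WT_12h replicate 2 and 1 without WT_12h replicate 1, KO_4h replicate 1, WT_16h replicate 2 or 4, or WT_20h replicate 2.

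At 16 h, 3 genes rose in KO (edgeR adjusted p = 0.0484 each). Pxdn, a matrix-associated peroxidase gene (chromosome 12, 30622901 to 30702523), was at 7.75 ± 1.54 CPM in WT (SD, n = 5) and 15.3 ± 1.4 CPM in KO (n = 3), a log2 change of 0.98 ± 0.18. It was lost in 34 alternatives, with changes between 0.91 and 1.08. The forkhead factor gene Foxp1 had a change of 0.95 ± 0.19 that came mostly from KO_16h replicate 2, since the KO values ran from 16.6 to 43.5 CPM and the change was 0.36 ± 0.16 without that library (adjusted p = 0.459). It was lost in 44 of 60 alternatives. The anion exchanger gene Slc4a9 had a change of 3.56 ± 0.70 that also came from this library, the one with high Lepr, since the KO values ran from 0.223 to 17.5 CPM and the change was −0.22 without that library. The count was 25, 0 and 7 without KO_16h replicates 1, 2 and 3, 0 without WT_16h replicate 1, 4 or 5, 1 without WT_16h replicate 2 or 3, and moved by over 1.5 times without any of 30 libraries of other times, to between 0 and 5. DESeq2 called 17 genes, and the edgeR count was 0 with the 16 h libraries alone.

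At 20 h edgeR called 0 genes, with 251 at an unadjusted p under 0.05 and 0 by DESeq2. The lowest p-values belonged to the neutrophil chemokine gene Cxcl1 (−1.99 ± 0.48), Dusp1 (−1.65 ± 0.42), the metalloproteinase inhibitor gene Timp3 (−1.11 ± 0.29), Junb (−1.68 ± 0.46) and the matrix Gla protein gene Mgp (−1.57 ± 0.43, but −0.99 ± 0.42 without WT_20h replicate 4), all lower in KO and not past the test. An effect past the threshold at some times and not at others is not shown to differ between them, and that difference was tested next.

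The genotype difference changed with time for 1 gene, Npas2, the paralogue of CLOCK that pairs with BMAL1 (interaction test of edgeR, adjusted p = 0.0302). Its KO minus WT change was 0.72 ± 0.48 at 0 h, −1.28 ± 0.51 at 4 h, 4.07 ± 0.83 at 8 h, 3.36 ± 0.83 at 12 h, 2.89 ± 0.64 at 16 h and 0.27 ± 0.49 at 20 h. In WT its level dropped to 0.0742 ± 0.0642 CPM at 8 h (SD, n = 4), where KO was at 1.38 ± 0.21 CPM (n = 4). DESeq2 called 11 genes. By edgeR 446 of 13646 had an unadjusted p under 0.05, a share below the 0.05 that chance alone gives on average. The count was 0 without WT_4h replicate 2, KO_4h replicate 2, 3 or 4, WT_8h replicate 1, 3 or 4, KO_8h replicate 1, 2 or 3, WT_12h replicate 1 or 3, KO_12h replicate 2 or 3, WT_16h replicate 1 or 4, or KO_16h replicate 2, and it was 2 without WT_12h replicate 2, WT_16h replicate 3 or KO_16h replicate 1 and 3 without KO_16h replicate 3.

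Both genotypes had large sets of rhythmic genes, led by the clock. In WT, among genes past the threshold with a mean of at least 1 CPM, the largest amplitudes belonged to Npas2 (3.12 ± 0.27, SE, log2 units), the clock-controlled transcription factor gene Dbp (2.69 ± 0.26), Arntl (2.34 ± 0.20), the repressor gene Gm129 (2.30 ± 0.27), Per3 (2.23 ± 0.18), Usp2 (2.19 ± 0.22), Cyp2b10 (2.15 ± 0.28) and Nr1d1 (2.04 ± 0.39), the gene of the repressor REV-ERBα. They were followed by the phosphate transporter gene Slc34a2 (2.03 ± 0.36), the matrix gene Npnt (1.94 ± 0.20) and the cell cycle inhibitor gene Cdkn1a (1.94 ± 0.25). In KO the amplitudes were 1.72 ± 0.23 for Npas2, 2.38 ± 0.30 for Dbp, 1.81 ± 0.21 for Arntl, 2.38 ± 0.21 for Per3 and 1.90 ± 0.40 for Nr1d1. Rhythmic genes numbered 2228 in WT and 2322 in KO by edgeR, and 1308 were in both sets, against 379 for independent sets of these sizes. Independence is not a full reference, as the libraries' main axis of variation had an R2 of 0.188 with collection time. This axis followed the libraries' GC slopes (r = 0.989), and a trend that both genotypes share could raise the overlap. DESeq2 gave 2701 and 2876. The KO count was 3687 without KO_16h replicate 3, and the test with 5 degrees of freedom gave 1167 and 1328. The 6 times cover less than 1 full cycle, so a rhythm of another period cannot be told from a 24 h one.

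Clock genes peaked earlier in KO by the fitted curves. Arntl peaked at 22.2 ± 0.3 h (SE) in WT and 20.9 ± 0.5 h in KO, Npas2 at 23.8 ± 0.3 and 22.6 ± 0.5 h, and the repressor gene Cry1 at 19 ± 0.3 and 18.1 ± 0.3 h. Per2 peaked at 13.3 ± 0.3 and 12.5 ± 0.3 h, Per3 at 11.3 ± 0.3 and 10.3 ± 0.4 h, Dbp at 9.63 ± 0.35 and 8.23 ± 0.50 h, and Nr1d1 at 7.31 ± 0.72 and 5.92 ± 0.79 h. Of 16 core clock genes 11 were rhythmic in WT and 12 in KO, and all 11 rhythmic in both peaked earlier in KO. Of 16 clock output genes 15 were rhythmic in WT, 13 in KO and 13 in both, of which 12 peaked earlier in KO, Upp2 by a shift of −1.68 h, and Por (15.1 ± 1.0 and 15.5 ± 1.3 h) later, though earlier by 0.41 h with the GC trend removed. Over the 24 genes of both lists the median shift was −0.934 h and 23 were earlier, a larger shift than in all but a share of 0.00180 of 100000 shuffles of genotype within time (permutation test, two-sided). Leaving out any single library kept the median between −1.04 and −0.813 h, and leaving out any time between −1.25 and −0.656 h.

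**Figure D4:**
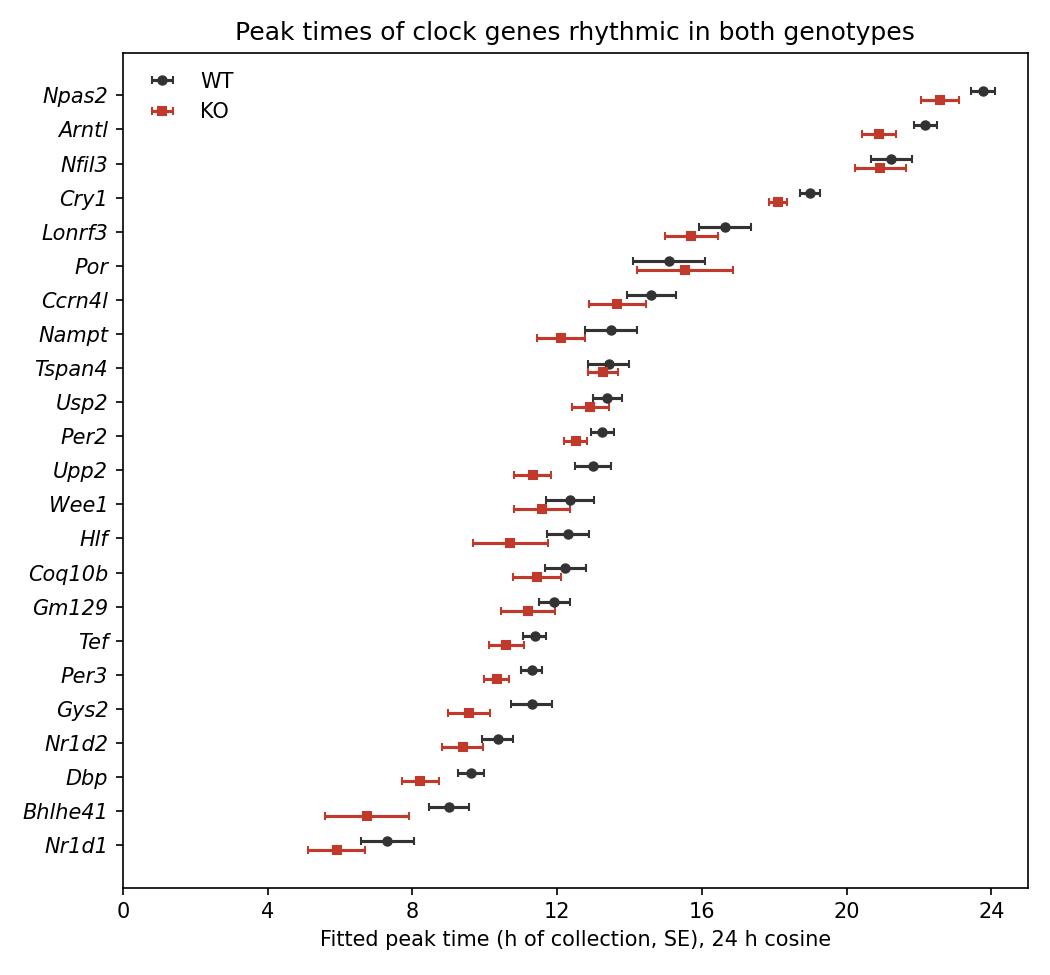
Fitted peak times of 23 of the 24 core clock and clock output genes rhythmic in both genotypes, in hours after the first collection with SE error bars, for WT and KO. The KO peak came earlier for 22 of the 23 genes plotted, from 22.2 to 20.9 h for Arntl, and later for Por, by less than the SE of either peak.

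In mean level across times, Npas2 rose and Gm129, also called Ciart (−1.28 ± 0.28, adjusted p = 0.0115), and Bhlhe40 (−0.65 ± 0.16, 0.0238), a helix-loop-helix repressor gene, fell among the 16 core clock genes. The other 13 did not pass by edgeR, and adjusted over the list alone 1 rose and 3 fell, with Bhlhe41 at −0.90 ± 0.29, which passed over all genes without KO_4h replicate 1 or KO_8h replicate 4 (edgeR adjusted p = 0.0489 and 0.0273). Bhlhe40 was lost without KO_16h replicate 3 (up to 0.0683). None of 16 clock output genes passed, also adjusted over the list alone, with Tspan4 at −0.25 ± 0.08, Usp2 at −0.46 ± 0.19 and Alas1 at −0.37 ± 0.18. Camera with an estimated correlation gave an adjusted p = 0.632 for the core clock and 0.495 for clock output.

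Rhythms in other groups were present in both genotypes. Of 16 heat shock genes 14 were rhythmic in WT, 9 in KO and 9 in both, and 1 of these peaked earlier in KO. Of 23 cholesterol synthesis genes 16 were rhythmic in WT, 7 in KO and 6 in both, and of 20 interferon-response genes 6, 10 and 4. These counts were not tested against each other, and no gene of these lists passed the test of a rhythm difference. Over all 1308 genes rhythmic in both, 954 peaked earlier and 354 later in KO, with a median difference of −0.731 h, and 1263 peaked within 3 h in both genotypes.

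The rhythm itself differed between the genotypes for 1 gene, Mpzl1, which encodes a cell surface protein related to myelin protein zero (chromosome 1, 167522312 to 167564672). Its amplitude was 1.54 ± 0.13 in WT and 0.75 ± 0.11 in KO, with peaks at 23.3 ± 0.3 and 20.7 ± 0.6 h (edgeR test of the difference, adjusted p = 0.00492). At 0 h it stood at 16.5 ± 6.4 CPM in WT and 9.60 ± 1.67 CPM in KO, and at 12 h at 1.64 ± 0.60 and 4.34 ± 0.89 CPM (SD, n = 4 each). Npas2 had the lowest p of the core clock genes, with an adjusted p = 0.146 over all genes and 6.9e-04 adjusted over the list alone. It passed over all genes by DESeq2 (adjusted p = 0.00177). DESeq2 called 5 genes, and the edgeR count was 2 without WT_16h replicate 2. By edgeR 363 of 13646 genes had an unadjusted p under 0.05, a share below the 0.05 that chance alone gives on average. The adjusted p of Mpzl1 was 0.113 in the interaction test, which has 5 degrees of freedom.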

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

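Chosen only after the results were seen were the tests of the GC trend on the difference across times, of a 15 Mb window, of a later collection time, of stromal cells and of a wrong label at 16 h, the fits with Alb, with the GC trend removed and without 3 libraries, and the added gene lists.

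Single libraries lay far from the rest of their group in 19 of 198 groups tested over 18 measures. By chance 9.9 are expected, but only for measures chosen without regard to the data and apart from each other. These included genes named for passing at single times, of which Cela2a, Star, Slc4a9 and Foxp1 owed their call mostly to 1 library. Cela2a is also a pancreas marker, so the 9.9 is no fair reference. WT_16h replicate 2 had a total of 13007696 counts, against 12841969 to 12883579 in the others, and 21.3 CPM of Arntl, against 13.8 to 15.4, which lies between the 19.2 and 36.1 CPM of the KO_16h libraries. A wrong label is possible, as the labels give 5 WT and 3 KO libraries at 16 h and the design text 4 each. It was tested with a genotype score, the mean log2 CPM, signed by direction, of 173 genes called across the other times. The score was 0.52 in this library, −0.23 to 0.20 in the other WT_16h libraries and 0.18 to 1.33 in KO_16h. These ranges overlap, and 5 of 48 libraries were nearer to the other genotype by their scores. At 27 of these genes that separate the other WT_16h from the KO_16h libraries, the library was nearer to the KO mean at 16, a share of 0.593, as a wrong label predicts, against at most 0.316 in the other WT_16h libraries treated the same way. It lay on the WT side of every KO_16h library at 13 of the 27, but KO_16h replicates 1, 2 and 3, treated the same way, lay on the WT side of the other KO_16h libraries at 19 of 26, 30 of 39 and 6 of 16, and their shares nearer to the KO mean, 0.282 to 0.75, overlap those of WT. WT_16h replicate 2 had a GC slope of −0.61 log2 units per 10 percentage points, against 0.37 to 0.58 in the other WT_16h libraries. In KO_16h the slopes were 0.12, 0.16 and −0.73. No score with the GC trend removed was run, so these genes cannot tell a wrong label from this trend. None of these values excludes a wrong label of WT_16h replicate 2. Across times 381 genes passed without this library, against 191 with it, so the values at 16 h and across times depend on its label. Cela2a was at 69.0 CPM in KO_0h replicate 2 (others 0.524 to 0.936) and at 0.0787 CPM in WT_0h replicate 1 (others 0.288 to 0.326), and the pancreas markers averaged 6.00 log2 CPM in the former (others 1.06 to 1.39) and 0.18 in the latter (others 0.66 to 0.73). Star was at 26.5 CPM in WT_0h replicate 3 (others 2.52 to 3.18). Dusp1 was at 137 CPM in WT_4h replicate 2 (others 25.7 to 43.2) and 39 CPM in KO_8h replicate 2 (others 13 to 17). Rec8 was at 1.26 CPM in KO_20h replicate 1 (others 0.309 to 0.451), Map4k4 at 15.2 CPM in KO_4h replicate 1 (others 10.4 to 10.9) and Slc4a9 at 5.86 CPM in WT_0h replicate 2 (others 1.08 to 1.81). Pxdn was at 11.5 CPM in WT_20h replicate 2 (others 10.95 to 11.03). Foxp1 was at 13.7 CPM in KO_0h replicate 3 (others 17.2 to 17.6) and 14 CPM in KO_12h replicate 1 (others 14.85 to 14.99).

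Mean marker levels also stood apart in single libraries. The adipocyte markers averaged 4.81 log2 CPM in KO_0h replicate 1 (others 5.10 to 5.11), and the stellate cell and fibroblast markers 3.09 in KO_0h replicate 4 (others 3.62 to 3.66) and 2.48 in WT_12h replicate 4 (others 3.24 to 3.39). The bile duct markers averaged 0.83 in WT_8h replicate 2 (others 1.76 to 1.90). The genotype difference of Npas2 changed with time (adjusted p = 0.0302 by edgeR's interaction test), and the rhythm of Mpzl1 differed between the genotypes (adjusted p = 0.00492).

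Other splits of the libraries were tested for each count. Shuffling genotype within time, 3 of 100 splits, the real one included, gave as many genes across times as the real 191, a share under 0.05. The highest other split gave 2834. The shares were not corrected for the number of counts tested, and the shuffles did not keep mice of the same number at 4 h apart. Chance is thus argued against only weakly. Chance cannot be excluded for the difference at 0 h (2 of 35 splits, real count 2, highest other 15), 4 h (3 of 35, real 5, highest other 2683) and 16 h (29 of 56, real 3, highest other 1871), nor for the interaction (13 of 100, real 1, highest other 2119) and the rhythm difference (27 of 100, real 1, highest other 1877). At 4 h, 8 splits part all 4 pairs of mice as the real one does, too few for a share under 0.05, and the highest other of these gave 0, while the highest of the 27 that keep some pair together gave 2683. A real count of 0 is reached by any split, so the splits decide nothing at 8 h (highest other 0), 12 h (2) and 20 h (0). With times shuffled within a genotype, the share was 2 of 100 for the rhythm in WT (real 2228, highest other 3198). For the rhythm in KO it was 1 of 100 (real 2322, highest other 84). Chance is argued against for both, but only weakly in WT, where another split called more genes. Splits that call several times the real count point to a structure of the libraries other than genotype, and the libraries differed in their GC trend by slopes from −0.80 to 0.60 log2 units per 10 percentage points, with 33.7% of the variance on a single principal component.

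The difference across times was weighed against technical explanations. With each library's GC trend removed, 188 genes passed and 139 of the 191 remained past the threshold, which argues against that trend as the whole source of the calls. A strain segment linked to the Cre transgene may contribute on chromosome 12, which held 16 called genes where 6.77 were expected, a concentration reached in a share of 0.0152 of random gene sets. The densest 15 Mb window was sought with the Mup genes and a predicted gene left out, in the called and the random sets. It ran from 16817771 to 31058240 on this chromosome, with 9 called of 34 tested genes, among them Rrm2, Odc1, E2f6, Cmpk2 and Pxdn. Zfp125 and 3110053B16Rik, also among the 9, overlap in position and may share reads. The window was matched in a share of 0.115 of random sets, so a segment and a dispersed change cannot be told apart by these counts. Genotype itself stays open as a biological explanation and was not tested apart from these.

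The earlier clock peaks in KO were weighed in the same way. A chance assignment of the mice is argued against by the share of 0.00180 of shuffles, the GC trend by a median shift of −0.939 h after its removal, and any single library by the shift closest to 0 with a library left out, −0.813 h. A later clock time of collection of the KO mice could give the same shift. The 9 rhythmic heat shock genes had a median shift of 0.635 h (permutation p = 0.508), which was 0.108 h without KO_0h replicate 4 and −0.148 h without the 0 h libraries, so its sign is uncertain. A gap as large as the −1.57 h between both medians arose in a share of 0.101 of shuffles, so this explanation and a shifted clock cannot be told apart.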

How the results depend on the processing

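Alternatives added after seeing the data were the fits with Alb, with the GC trend removed and without 3 unusual libraries (WT_0h replicate 3, KO_0h replicate 2, KO_16h replicate 2). Of 97 named results past the threshold, 68 kept their side of it in every alternative run, and over 5847 comparisons 5392 were on the same side in the same direction, 453 missed the threshold and 2 changed sign. These were Slc4a9 at 16 h, at −0.19 without the 3 libraries and −0.22 without KO_16h replicate 2, the lowest value with a library left out (highest 4.16). The cause of a change was not tested unless named.

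The 191 genes across times became 122 with no filter, 53 at a mean of at least 10 CPM (fewer genes tested), 356 by DESeq2 and 303 without the 3 libraries, where 174 remained. The 2 genes at 0 h became 5 with RLE factors, 10 with no filter, 0 with the stricter filter, 11 by DESeq2, 1 with the library number as covariate, 1 without the 16 h groups, 5 with Alb, 9 with the GC trend removed, 8 without the 3 libraries and 0 with the 0 h libraries alone. The 5 genes at 4 h became 2 with no filter, 1 with the stricter filter, 192 by DESeq2 (114 higher, 78 lower), 1 with the library number, 543 without the 16 h groups, 8 without the 3 libraries and 0 with the 4 h libraries alone. The count of 0 at 8 h became 2 by DESeq2. The count of 0 at 12 h became 3 by DESeq2 and 1 with no filter, without the 16 h groups or with the GC trend removed. The 3 genes at 16 h became 17 by DESeq2 and 0 with totals only, either other filter, the library number, Alb, without the 3 libraries or with the 16 h libraries alone. The interaction count of 1 became 11 by DESeq2 and 0 with the stricter filter or without the 3 libraries. The rhythm counts became 1477 in WT with the stricter filter and 1167 in WT and 1328 in KO with 5 degrees of freedom. The rhythm difference became 0 with the stricter filter and 5 by DESeq2. The list count of 0 became 6 with the preset correlation and 1 with fry.

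Leaving out each library in turn gave 99 to 484 genes across times, 0 to 9 at 0 h, 0 to 3354 at 4 h, 0 to 1 at 8 h, 0 to 2 at 12 h, 0 to 25 at 16 h, 0 to 3 for the interaction, 1629 to 3687 for the rhythm in KO and 1 to 2 for the rhythm difference. The rhythm count in WT stayed between 1875 and 2986, and counts at 20 h and over lists stayed at 0.

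Outside 4 h the replicate numbers were not taken to pair the mice, and 9 of 23 KO libraries correlated best with their own number. With these numbers as a block, 127 genes passed across times, 107 of them among the 191, and counts were 0 at 0 h, 2 at 4 h, 0 at 16 h and 0 for the interaction. Of the named calls across times, Cyp3a16, Mup15, Gadd45g, Ighm, Bhlhe40, Vnn1, Cyp2c37, Isg15 and Gbp3 were then not past the threshold, and at 4 h Rec8 alone kept its call. Depth limits the results for genes under 1 CPM, which made up 28 of the 191.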

Other observations

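All gene lists of this part were chosen only after the results were seen, except the stellate cell and fibroblast markers, as was the test of stromal cells. Lists chosen for their genes cannot test whether they differ as groups, so no p-value is given for them. For the same reason, counts adjusted over such a list alone only describe its members and count as no support.

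Immediate early genes, which are transcribed within minutes of a stimulus without new protein synthesis, were among the genes lower in KO liver. Of 35 tested, 33 had a negative change across times and 8 fell: Dusp1, Fos, Jun, Gadd45g, Junb (−1.15 ± 0.19), the AP-1-related Csrnp1 (−1.02 ± 0.21), the RNA-decay factor gene Zfp36 (−1.04 ± 0.21) and the antiproliferative Btg2 (−0.82 ± 0.19). Adjusted over the list alone, 21 fell. Nr4a1 (−1.17 ± 0.35) and Egr1 (−0.82 ± 0.28) did not pass over all genes. The 27 members that did not pass had a median of −0.30, with 25 negative. Whether the whole list is lower, and not its called members alone, is a hypothesis that these data cannot decide, and how the mice were handled before death stays open.

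Of 39 tested genes of the extracellular matrix and portal stroma, 34 had a negative change, 17 fell and 1 rose. Timp3 fell by 1.04 ± 0.12, the actin-severing Gsn by 0.83 ± 0.15, the complement gene C7 by 1.68 ± 0.33, Mgp by 0.87 ± 0.19 and the fibulin gene Fbln2 by 0.72 ± 0.18, while the cross-linking enzyme gene Lox rose by 1.34 ± 0.27. Adjusted over the list alone, 25 fell and 3 rose. Fewer stromal cells in the KO pieces would lower all markers of these cells alike. The fixed stellate cell and fibroblast markers had a median of −0.14 (SD 0.22 over 12 members), lower than in all but a share of 0.0354 of random lists. These lists were drawn gene by gene, so the share does not allow for markers that vary together. Camera with an estimated correlation, which does, gave these markers a p of 0.256 (adjusted p = 0.512). The matrix genes had a median of −0.55, but they were listed after the results were seen, and those not past the threshold had a median of −0.35. Fewer stromal cells and a genotype effect on expression thus both stay open.

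Of 15 tested Mup genes, which encode urinary pheromone-binding proteins made in liver, 13 had a positive change and 6 rose (Mup17, Mup2, Mup12, Mup15, Mup16 and Mup1, the pseudogene Mup-ps14 not being on the list), 10 adjusted over the list alone. Mup20 (−0.06 ± 0.27) and Mup21 (−0.08 ± 0.22) did not pass. Reads that these copies may share make single members uncertain. Of 5 tested adrenal cortex markers none passed over all genes, and 1 fell adjusted over the list alone, with Star at −0.66 ± 0.20, but at −0.39 ± 0.14 without WT_0h replicate 3, the library with adrenal transcripts. Albumin, which was left out of the tests, had a log2 KO minus WT difference of −0.11 (two-sided permutation test over libraries within time, p = 0.306).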
